A study of Rattus norvegicus with 6 samples.

How the data were processed

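Kidney inner medulla of male Sprague-Dawley rats was measured on 6 Affymetrix whole-transcript gene arrays, one per sample, in 3 groups of 2 (vehicle, dDAVP for 5 d, and 3 h after removal of the minipump). RNA was extracted with Trizol and labelled by whole-transcript sense target labelling, per the labels' protocols. The authors summarised the probes with RMA, per the submitters' processing notes, and deposited 1 value per probe set and array. The version of RMA and the genome build are not given in the sources used here. The deposited values are intensities on a linear scale (from 30.2 to 10778.7), although RMA usually gives log2 values, so the log2 of each value was taken before any test. The plan had assumed values on a log2 scale. RMA normalizes the distribution of probe intensities between arrays, so a change that moved most genes the same way would be reduced in these values. The arrays' median intensities nevertheless ran from 156 to 182. Detection calls, scan dates and slide identities were not used here, so batches could not be looked for, and how far a probe set lay above background is unknown.

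The table held 28524 probe sets. In the annotation table of the array, 14947 carried exactly 1 gene symbol, 318 carried several and 13259 were not listed there, which leaves them unnamed here. The Entrez numbers of 14916 of the single-symbol probe sets were found in the RefSeq gene table of assembly GRCr8, which was used for names only, and it changed 0 symbols. For each gene the probe set with the highest mean over the 6 arrays was used, which gave 14168 genes, 509 of them with more than 1 probe set. No filter on dim genes was applied. Members of the gene lists with an older symbol were matched through the synonyms of the same table.

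The groups were compared with limma 3.58.1 in R 4.3.3. One linear model with 1 mean per group was fitted to all 6 arrays (lmFit), so that the groups shared 1 estimate of the spread, with 3 residual degrees of freedom per gene and 3.21 prior degrees of freedom from eBayes. All tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The 3 comparisons and a moderated F-test over the groups made 4 families of tests. An added descriptive count, not corrected for multiple tests, took genes at least 1.5-fold apart with an unadjusted p under 0.05. Means are given ± SD of the 2 arrays and differences ± the moderated standard error.

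The study's comparisons, the 41 gene lists (27 of function and 14 of cell type markers), the tests, most alternatives and the rule for the genes named were fixed before the data were examined. Lists were tested with camera and a preset correlation of 0.01, for lists with at least 5 measured members, with the adjustment over all 41 lists of a comparison. The same test with a correlation estimated for each list, and fry, stand beside it. With an estimated correlation and with fry no list was called in any comparison (smallest adjusted p with an estimated correlation 0.560, 0.523 and 0.786, and with fry 0.306, 0.170 and 0.948, in the order of the report). A camera call of a list says how its genes moved against all other genes, which differs from a move against 0 where the median gene moves. Beside each count over all genes, members of a list were also adjusted over the list alone. This gave 16 genes in 4 lists in withdrawal against dDAVP and none in the other comparisons.

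Genes were named by a rule of 3 parts. Since no gene passed, the first part named for each comparison the 8 higher and 8 lower genes with the smallest unadjusted p among those at least 1.5-fold apart whose arrays did not overlap between the groups, leaving out symbols of unnamed loci, olfactory and vomeronasal receptors and microRNAs. Chance alone separates 2 arrays from 2 others without overlap in 33.3% of genes, and 45.4%, 57.6% and 30.7% of genes were separated so in the 3 comparisons. The second part named a fixed set of transport, signalling and ubiquitin ligase genes, of which 1 is not reported here, and the third up to 4 passing members of each called list or, with none, the 2 with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen, except members of the interferon list, which are named where they passed within that list or as further examples.

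The gene test and the list test were tested on simulated data before use. Arrays were simulated with each gene's residual variance over all 3 groups, and 200 of 14168 genes were changed in the dDAVP arrays. In dDAVP against vehicle the gene test recovered 0% at 0.58 log2, 65% at 1 log2 and 94% at 2 log2. A simulated fall of the interferon list by 0.3 log2 in the same comparison was recovered (camera, adjusted p = 5.1e-12), and 1 other list was called with it. The genes were simulated as independent, so this recovery does not show how the list test behaves with correlated genes.

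The alternatives were dropping the dimmest genes by mean level (at a milder and a stricter share of the genes), cyclic loess or subtraction of array medians, an intensity trend or robust eBayes, array weights, every probe set, the mean over a gene's probe sets, the replicate number as a block, only the 4 arrays compared, an ordinary unmoderated contrast, and leaving out each array in turn. Leaving out both arrays that stand apart, a crossed pairing, and cyclic loess with an estimated correlation were added after the data were seen. The replicate numbers in the labels are not said to mark shared animals, litters or days. For the reversal after withdrawal, 1000 sets of unchanged arrays were simulated with each gene's residual variance, taken as equal in the 3 groups.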

Results

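Total RNA of the kidney inner medulla, the innermost zone of the kidney where the collecting ducts end, was measured on 6 whole-transcript gene arrays, 2 for each of 3 groups of male Sprague-Dawley rats. The vehicle group received saline at 1 µl/h under the skin for 5 d from an osmotic minipump. The dDAVP group received 40 ng/h of dDAVP (desmopressin, an agonist selective for the vasopressin V2 receptor of the collecting duct) for 5 d. In the withdrawal group the minipump was taken out under light enflurane anaesthesia after the same infusion, and the tissue was collected 3 h later. The deposited intensities ran from 30.2 to 10778.7, and 14168 genes with a symbol of their own were compared on the log2 scale. The number of arrays, 2 in each group, limits the precision of every value. The labels do not say that the arrays of a group hold separate animals, so the p-values measure the spread between these arrays only.

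The 6 arrays differed in brightness and in the levels of a set of genes. The median intensity was 182 and 175 in the vehicle arrays, 156 and 165 in the dDAVP arrays, and 182 and 181 in the withdrawal arrays. The median log2 difference over all genes was -0.11 for dDAVP against vehicle, 0.14 for withdrawal against dDAVP and 0.03 for withdrawal against vehicle, with the larger shifts among dim genes. Among genes of the third of 10 classes of expression level the median difference of dDAVP against vehicle was -0.18, against -0.02 in the brightest class. Differences are therefore given as deposited and, where it matters, after a cyclic loess normalization that brings the median gene to within 0.01 of 0. Vehicle replicate 1 and dDAVP replicate 2 also stood apart from the other 4 arrays. Mest, an imprinted gene, had log2 intensities of 5.47 and 5.66 in these 2 arrays and of 9.97 to 11.10 in the other 4. The cell cycle genes Cdk1 (7.37 and 7.26 against at least 8.90) and Top2a (7.07 and 6.83 against at least 8.59) were also lower in them, whereas Spink13 was higher (9.11 and 8.93 against at most 6.83). In 40 genes these 2 arrays lay more than 1 log2 away from all of the other 4, and no other pair of arrays reached more than 2 such genes. These 4 genes were chosen after their values were seen.

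**Figure D1:**
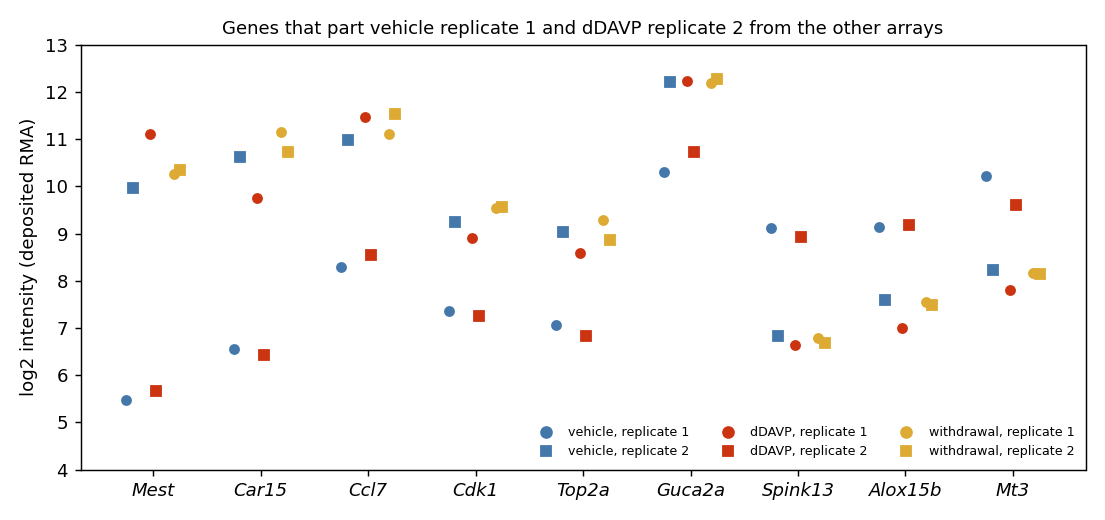
Log2 intensity of 9 genes in each of the 6 arrays, coloured by group with a symbol for each replicate number. Vehicle replicate 1 and dDAVP replicate 2 lie together and away from the other 4 arrays, with Mest at 5.47 and 5.66 in them and at 9.97 or above elsewhere.

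**Figure D2:**
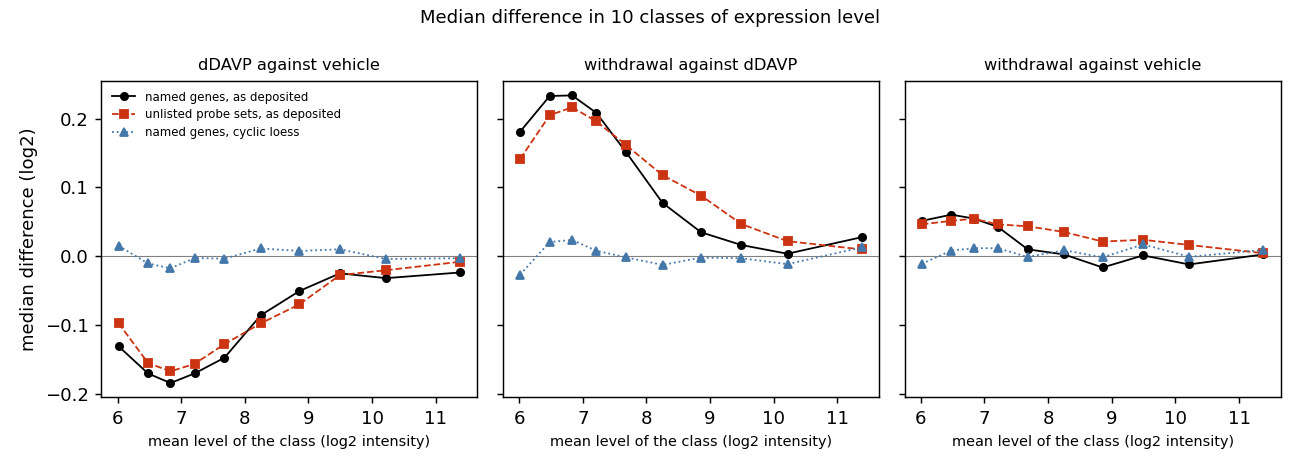
Median log2 difference of each comparison in 10 classes of mean expression level (x axis, log2 intensity), for named genes and for probe sets with no listed gene as deposited, and for named genes after cyclic loess. In dDAVP against vehicle the median is -0.18 in the third class and -0.02 in the brightest, and the probe sets with no listed gene follow the same course.

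The first comparison, dDAVP against vehicle, asked what 5 d of V2 receptor stimulation does to the inner medulla transcriptome. The interferon response genes, which cells switch on through type I interferon signalling, fell as a list after the infusion. Their median log2 difference was -0.31 as deposited and -0.28 after cyclic loess, with 24 of the 25 measured members below 0 after loess. Ifih1, a sensor of viral RNA, had a log2 intensity of 9.59 ± 0.02 in vehicle and 9.01 ± 0.10 in dDAVP (SD, n = 2), a difference of -0.58 ± 0.16 (SE). The transcription factor Irf1 went from 8.78 ± 0.11 to 8.27 ± 0.08, a difference of -0.51 ± 0.13. As further examples among the larger falls, Isg15, a ubiquitin-like modifier, differed by -0.52 ± 0.24 and Ifit3 by -0.53 ± 0.35. Gbp2 went from 10.64 ± 0.22 to 10.14 ± 0.11, a difference of -0.50. In 16 of the 25 members both dDAVP arrays lay below all 4 other arrays, and the count was also 16 after loess. Chance gives this order to a single gene with a share of 0.0667, 1 of the 15 ways to choose 2 of the 6 arrays. That share assumes no shift common to all genes, whereas the dDAVP arrays had the lowest medians, and the members are correlated. The share of all genes with this order was not computed. The list passed the camera test of limma with a preset correlation (adjusted p = 0.0023, and 4.9e-10 after loess), and had an adjusted p = 0.623 with an estimated correlation between its genes. No member passed, neither over all genes nor adjusted over the list alone. Immune cell markers, which were not called in this comparison (adjusted p = 0.865, and 0.266 after loess), had a median difference of -0.11 after loess, with 16 of 24 below 0. The call of the interferon list was lost without vehicle replicate 2 (adjusted p = 0.249), where the median difference was -0.20 with 23 of 25 members below 0, against -0.14 for the median gene. It was kept without any other single array and without the 2 arrays that stand apart (adjusted p = 0.0021).

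The genes of water and urea transport showed smaller differences than their spread allowed to be called. Aqp2, the vasopressin-regulated water channel of the collecting duct and the brightest probe set of both dDAVP arrays, was at 13.19 ± 0.05 in vehicle and 13.35 ± 0.07 in dDAVP, 1.11-fold apart, with both dDAVP arrays above both vehicle arrays (difference 0.15 ± 0.10 SE, adjusted p = 0.558). Whether its signal lay near a ceiling was not tested. Avpr2, the V2 receptor itself, was at 11.45 ± 0.19 and 11.67 ± 0.06 (difference 0.22 ± 0.16, adjusted p = 0.584). The water channel Aqp4 differed by -0.02 ± 0.21, the urea transporter Slc14a2 by -0.01 ± 0.30 and the sodium channel subunits Scnn1b and Scnn1g by -0.17 ± 0.17 and -0.20 ± 0.14. The signs of Aqp4 and Slc14a2 turned when the array medians were subtracted (0.10 and 0.11), and that of Slc14a2 also after loess (0.01). The list of 9 measured water and urea transport genes was not called (adjusted p = 0.102). Aqp3 was not analysed here, since no probe set carried its symbol alone.

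**Figure D3:**
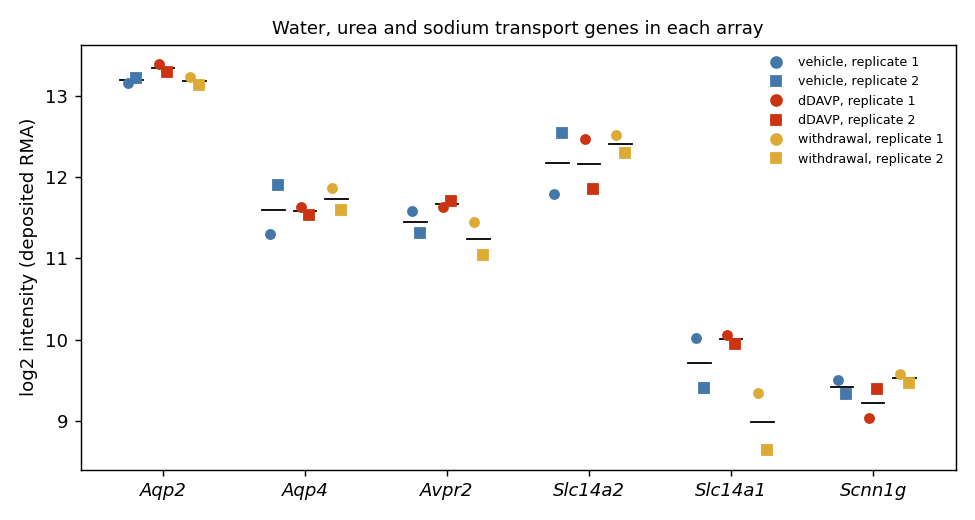
Log2 intensity of 6 transport genes in each array, with a bar at the mean of each group of 2. Aqp2 lies between 13.30 and 13.40 in dDAVP and between 13.14 and 13.23 in the vehicle and withdrawal arrays, and Slc14a1 has its lowest values, 8.64 and 9.34, in the withdrawal arrays.

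Across all 14168 genes none passed an adjusted p of 0.05 in limma for dDAVP against vehicle (smallest adjusted p 0.549). At an unadjusted p under 0.05 there were 1052 genes, 81 higher and 971 lower, where chance alone gives 708.4. There were 460 genes after loess, 252 higher and 208 lower, and 495 genes with array medians subtracted, 372 of them higher. The count was 561 without vehicle replicate 1, 1626 without vehicle replicate 2, 379 without dDAVP replicate 1 and 641 without either 1 of the withdrawal arrays. At least 1.5-fold apart with an unadjusted p under 0.05 were 6 higher and 25 lower genes, or 8 and 9 after loess, and this count of 31 became 100 without vehicle replicate 1, 88 without vehicle replicate 2, 65 without dDAVP replicate 1 and 370 without dDAVP replicate 2. The 8 genes with the smallest p among those higher by 1.5-fold or more, none of which passed, differed by 1.51 to 1.83-fold. They were Fmo5, a flavin-containing monooxygenase (0.87 ± 0.23), the protease inhibitor Spink8 (0.87 ± 0.29), Ccng1 (0.73 ± 0.28), the adaptor Crk (0.66 ± 0.20), the membrane oestrogen receptor Gper1 (0.64 ± 0.22), the proteoglycan Sdc4 (0.63 ± 0.26), Zmym6 (0.62 ± 0.22) and Cfap141 (0.59 ± 0.26). The other probe set of Zmym6 gave 0.01. Spink8 was lowest of the 6 arrays in vehicle replicate 2, at 6.52, against 7.42 in vehicle replicate 1 and 7.65 and 8.04 in dDAVP. Among the 8 lower genes, 1.51 to 1.96-fold apart and none passing, were the mitochondrial co-chaperone Dnaja3 (-0.97 ± 0.23), the replication factor Gins1 (-0.67 ± 0.14), Chchd5 (-0.66 ± 0.12), Abhd3 (-0.62 ± 0.12), Taf9b (-0.62 ± 0.14), Sass6 (-0.61 ± 0.09), Snx10 (-0.61 ± 0.11) and the chemokine Cxcl13 (-0.60 ± 0.09). After loess these 8 differences ran from -0.93 for Dnaja3 to -0.43 for Cxcl13. With dDAVP replicate 1 left out, 2 genes passed, Ypel4 (difference 4.89, adjusted p = 0.000465) and Fam111a (-3.76, adjusted p = 0.0265), both of which were extreme in dDAVP replicate 2 alone (11.89 and 6.77, against at most 7.06 and at least 10.50 in the other 5 arrays).

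A further 15 lists were called in the direction of higher levels in dDAVP, with adjusted p-values from 0.00099 to 0.0177 by camera with the preset correlation. They were cAMP and protein kinase A signalling, immediate early genes, osmoprotective NFAT5 target genes, E3 ubiquitin ligases, cullin and F-box ligase subunits, deubiquitinases, lysosome and endosomal sorting, the prostaglandin system, heat shock genes, hypoxia responsive genes, glycolysis, mitochondrial oxidative phosphorylation, ribosomal proteins, and the markers of intercalated cells and of the thick ascending limb. Camera sets a list against all other genes, and 10 of these 15 lists had a median difference below 0, only less so than the median gene. Their medians ran from -0.03 to 0.20 as deposited and from -0.01 to 0.28 after loess. After loess none of the 15 was called (adjusted p from 0.264 to 0.912) and the ribosomal list turned the other way, and with an estimated correlation their adjusted p-values ran from 0.560 to 0.760. Without vehicle replicate 1 all 15 calls were lost, without dDAVP replicate 1 8, without dDAVP replicate 2 4 and without both arrays that stand apart 12. With single arrays left out 13 of the 15 medians crossed 0, within a range from -0.21 to 0.53. Intercalated cell markers turned the other way without vehicle replicate 1 (median -0.15, from 0.16, adjusted p = 0.933), immediate early genes without dDAVP replicate 1 (median -0.21, from 0.01, adjusted p = 0.331) and thick ascending limb markers without both arrays that stand apart (adjusted p = 0.780). None of their members passed. A list called after loess but not as deposited was that of proteasome subunits, which was lower in dDAVP (adjusted p = 0.0087, 30 of 38 members below 0, median -0.10, adjusted p = 0.991 with an estimated correlation).

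Ubiquitin ligases were of interest to the study, which is known to have looked at E3 ligases in these rats, so the list is not independent of that interest, although its members were fixed from general knowledge. Of the 131 measured E3 ligases none passed, and 4 were higher and 10 lower at an unadjusted p under 0.05. Rnf167 was at 10.56 ± 0.06 in vehicle and 10.93 ± 0.05 in dDAVP (difference 0.37 ± 0.10), and Rnf6 at 7.99 ± 0.04 and 7.56 ± 0.19 (-0.43 ± 0.12). Nedd4 differed by -0.09 ± 0.09, Nedd4l, which acts on the epithelial sodium channel, by -0.01 ± 0.15, Rnf40 by -0.25 ± 0.10 and Mylip by 0.17 ± 0.13. When the array medians were subtracted Nedd4 and Nedd4l were at 0.03 and 0.11, and after loess Nedd4l was at 0.02. Stub1 was not analysed here. Among the deubiquitinases Josd1 differed by 0.48 ± 0.10 and Usp4 by -0.51 ± 0.15, and the anaphase-promoting complex subunit Anapc10 by -0.46 ± 0.11. Other members of the called lists were Plk2 (-0.65 ± 0.22) and Klf10 (-0.42 ± 0.14) among immediate early genes, Fos (0.18 ± 0.40), Nfat5 (-0.58 ± 0.18), the amino acid transporter Slc38a2 (0.40 ± 0.17), the kinase Sgk1 (0.10 ± 0.20), the carbonic anhydrase Car9 (-0.36 ± 0.10) and the phosphodiesterase Pde3a (-0.31 ± 0.11). The prostaglandin E receptor Ptger3 was at 0.26 ± 0.15, lactate dehydrogenase Ldha at 0.16 ± 0.10 and the ATP synthase subunit Atp5mc3 at 0.20 ± 0.09. The other probe sets of Ldha and Atp5mc3 gave 0.04 each. The other members with the smallest p of these lists were higher for Slc4a1 (0.75), Chordc1 (0.33), Chmp1a (0.24), Rpl10 (0.20), Hk1 (0.17) and Npc1 (0.15), and lower for Tmem72 (-0.36), Pkia (-0.28), Pfkfb4 (-0.25), Cbr1 (-0.24), Skp2 (-0.21), Rpl11 (-0.20), Slc26a4 (-0.18), Sdhc (-0.18) and Hspb1 (-0.18), and none of them passed. The heat shock gene Hspa1a was not analysed here.

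The second comparison, withdrawal against dDAVP, asked what differed 3 h after the minipump was taken out. A removal under anaesthesia is described for the withdrawal group only. The end of the infusion and this procedure therefore cannot be told apart. This comparison holds the same 2 dDAVP arrays as the first. A chance level of these arrays alone would give opposite differences in the 2 comparisons. A gene or list that fell in the first and rose here, or the reverse, is therefore not 2 independent results. The interferon response genes rose as a list, with a median difference of 0.45 as deposited and 0.43 after loess, and 24 of 25 members above 0 after loess. Of the 25 members 12 passed when adjusted over the list alone (9 after loess), and none over all genes. These 12 were Oasl (0.91 ± 0.18), Irf1 (0.58 ± 0.13), Usp18, which removes Isg15 from proteins (0.60 ± 0.14), the RNA sensors Ifih1 (0.64 ± 0.16) and Rig1 (0.45 ± 0.12), Isg15 (0.84 ± 0.24), the transcription factor Irf7 (0.54 ± 0.15), Ifit2 (0.58 ± 0.17), Ifit3 (1.07 ± 0.35), the antiviral GTPase Mx2 (0.44 ± 0.13), Rsad2 (0.56 ± 0.18) and Cmpk2 (0.63 ± 0.21). Withdrawal replicate 2 had the highest level of the 6 arrays in each of these 12 genes, for example 11.89 for Ifit3 against 10.78 in withdrawal replicate 1. Without withdrawal replicate 2 the median difference of the list was 0.28, with 23 of 25 members above 0, and without withdrawal replicate 1 it was 0.71. The list was called by camera with the preset correlation (adjusted p = 0.000288, and 2.8e-13 after loess) and had an adjusted p = 0.648 with an estimated correlation. Its call held without any single array, with adjusted p at most 0.0060, and without the 2 arrays that stand apart (0.0026). Leaving out Usp18, Psmb8 and Psmb9, which other lists also hold, 22 members remained and their unadjusted camera p was 4.9e-05.

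**Figure D4:**
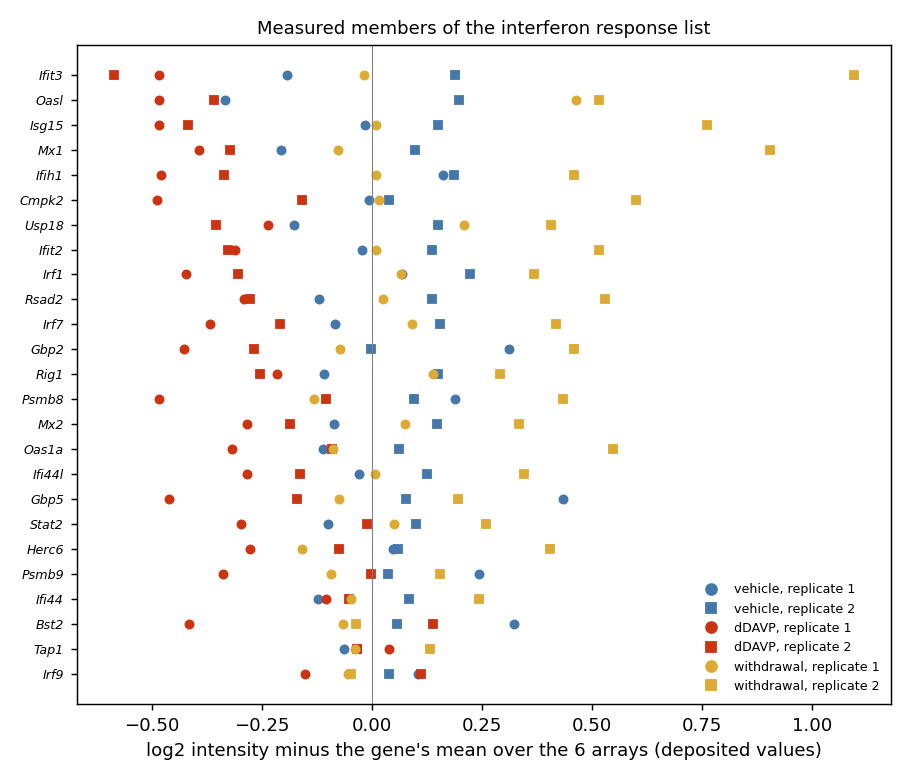
Log2 intensity of each of the 25 measured interferon response genes minus its mean over the 6 arrays (x axis), as deposited, with a point for each array. The dDAVP arrays lie lowest in 16 of the 25 genes. Ifit3, at 11.89 in withdrawal replicate 2 before its mean was subtracted, has the widest range.

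The cell cycle genes and the inflammatory response genes were the other lists called higher after withdrawal. The cell cycle list had a median difference of 0.72 as deposited and 0.56 after loess, with all 32 members above 0 after loess, among them the replication helicase subunit Mcm6 (0.78 ± 0.17) and the mitotic kinase Aurkb (0.74 ± 0.20). It was called with an adjusted p of 0.0016 by camera, 1.7e-07 after loess, and an adjusted p = 0.694 with an estimated correlation. The 2 dDAVP arrays differed widely in this list (loess medians of 0.12 and -0.56 around the mean of the 6 arrays), since dDAVP replicate 2 is an array that stands apart, and the call was lost without it (adjusted p = 0.225, median 0.32) or without withdrawal replicate 1 (0.0525). The inflammatory list had a median of 0.34 (0.22 after loess, with 23 of 26 members above 0). The cytokine Lif (0.57 ± 0.12, and 0.36 after loess) and the complement component C3 (0.41 ± 0.09, and 0.20 after loess) passed as deposited when adjusted over the list alone. The inflammatory list was called by camera with an adjusted p of 0.0462 (0.00086 after loess), and had an adjusted p = 0.677 with an estimated correlation. Its median was 0.29 without dDAVP replicate 2 (20 of 26 members above 0), against 0.17 for the median gene. Without withdrawal replicate 2 it was 0.27 (23 of 26), against 0.13 for the median gene. It lost its call without either vehicle array (0.0853), without dDAVP replicate 2 (0.770) and without withdrawal replicate 2 (0.0715), and without both arrays that stand apart it pointed the other way (0.818). Markers of fibroblasts (Postn, 0.73 ± 0.14) and of adipocytes (Adipoq, 0.37 ± 0.09) gave 1 gene each that passed adjusted over its list alone, in lists that were not called. After loess Postn was at 0.52 and Adipoq at 0.16.

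Of the transport genes, the urea transporter Slc14a1 was at 10.01 ± 0.08 in dDAVP and 8.99 ± 0.50 in withdrawal, 2.02-fold lower (difference -1.02 ± 0.28, adjusted p = 0.260). Avpr2 differed by -0.43 ± 0.16 (adjusted p = 0.260) and Aqp2 by -0.16 ± 0.10 (adjusted p = 0.343), and for both the withdrawal arrays lay below the dDAVP arrays. Slc14a2 was at 0.25 ± 0.30, Aqp4 at 0.15 ± 0.21, Scnn1b at 0.25 ± 0.17, Scnn1g at 0.31 ± 0.14, Sgk1 at -0.07 ± 0.20 and Fos at 0.36 ± 0.40. The list of water and urea transport was not called (adjusted p = 0.106). None of these genes passed.

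No gene passed over all 14168 in withdrawal against dDAVP (limma, smallest adjusted p 0.260). At an unadjusted p under 0.05 there were 2686 genes, 2454 higher and 232 lower, 922 after loess, 452 higher and 470 lower, and 1266 with array medians subtracted, 366 of them higher. The count was 1624 without dDAVP replicate 1, 1571 without withdrawal replicate 1 and 773 without withdrawal replicate 2. At least 1.5-fold apart with an unadjusted p under 0.05 were 109 higher and 14 lower genes, or 40 and 24 after loess, and this count of 123 became 506 without dDAVP replicate 1, 216 without dDAVP replicate 2 and 394 without withdrawal replicate 1. The 8 higher genes with the smallest p, none passing, were the monocyte chemokine Ccl12 (1.06 ± 0.17), Gins1 (0.90 ± 0.14), Slfn9 (0.87 ± 0.16), Tm4sf20 (0.78 ± 0.12), podoplanin (Pdpn, 0.71 ± 0.09), the protease Mmp12 (0.69 ± 0.12), Snx10 (0.64 ± 0.11) and the histone methyltransferase Ezh2 (0.63 ± 0.10). The 8 lower genes were Wfdc10a (3.32-fold, -1.73 ± 0.39), Slc14a1, Sdc4 (-0.91 ± 0.26), Tcf7l1 (-0.69 ± 0.20), Crk (-0.66 ± 0.20), Clec2l (-0.63 ± 0.13), Rhog (-0.63 ± 0.21) and the clock gene Cry2 (-0.62 ± 0.14). The 2 other probe sets of Tcf7l1 gave -0.22 and 0.13. With dDAVP replicate 1 left out, Ypel4 (-5.00) and Fam111a (4.12) passed here too.

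A further 9 lists were called lower in withdrawal against dDAVP (adjusted p from 4.4e-05 to 0.0344). They were AQP2 trafficking machinery, osmoprotective NFAT5 target genes, E3 ubiquitin ligases, cullin and F-box ligase subunits, deubiquitinases, glycolysis, mitochondrial oxidative phosphorylation, and the markers of the thick ascending limb and of endothelium. Their median differences ran from -0.09 to 0.03 as deposited, against 0.14 for the median gene. With single arrays left out 8 of the 9 medians crossed 0, within a range from -0.26 to 0.16, with -0.26 and 0.12 for the thick ascending limb and -0.15 and 0.16 for endothelium without dDAVP replicate 1 and without dDAVP replicate 2. After loess none of the 9 was called (adjusted p from 0.0698 to 0.878), and with an estimated correlation their adjusted p-values ran from 0.523 to 0.656. E3 ligases and cullin and F-box subunits had loess medians of -0.05 and -0.06, with 81 of 131 and 52 of 72 members below 0 and an adjusted p of 0.0698 each. Rnf167 differed by -0.50 ± 0.10 and Brca1 by 0.39 ± 0.09, Rnf40 by 0.34 ± 0.10, Mylip by -0.30 ± 0.13, Nedd4 by -0.13 ± 0.09 and Nedd4l by -0.01 ± 0.15. Josd1 was at -0.46 ± 0.10, the moesin gene Msn at -0.27 ± 0.11, the taurine transporter Slc6a6 at -0.43 ± 0.15, the lactate transporter Slc16a3 at -0.30 ± 0.11 and the endothelial receptor Tek at -0.55 ± 0.19. The other members with the smallest p were Egf (-0.72), Slc38a2 (-0.47), Pfkl (-0.40), Fbxl20 (-0.27), Atp5mc3 (-0.22), Slco1c1 (0.25), Ndufb10 (0.31), Tmem72 (0.36), Anapc10 (0.38) and Rab11fip2 (0.40). The Egf difference came from dDAVP replicate 2, at 10.34, against 8.64 in dDAVP replicate 1 and 8.96 and 8.58 in the withdrawal arrays. The other probe sets of Fbxl20 and Atp5mc3 gave -0.14 and -0.06. Apart from Usp18, which is also a deubiquitinase and passed in the interferon list, none of the members passed. Of the 9 calls 5 held without each single array. AQP2 trafficking lost its call without dDAVP replicate 2 (adjusted p = 0.0982) or withdrawal replicate 1 (0.0730), and NFAT5 target genes without dDAVP replicate 1 (0.327). The thick ascending limb lost it without either vehicle array (0.0532), dDAVP replicate 2 (0.785) or withdrawal replicate 2 (0.376), and endothelium without dDAVP replicate 2 (0.668) or withdrawal replicate 2 (0.0688). Called after loess only were proteasome subunits (higher, median 0.13, adjusted p = 0.00035), ribosomal proteins (higher, 0.09, adjusted p = 0.0292) and proximal tubule markers (lower, -0.14, adjusted p = 0.0072). The 2 rises came mostly from withdrawal replicate 2. The loess medians of withdrawal replicates 1 and 2 were -0.03 and 0.16 for the proteasome, against -0.10 and -0.08 in dDAVP. For ribosomal proteins they were -0.01 and 0.10, against -0.02 and -0.03. No list was called after loess with an estimated correlation (smallest adjusted p = 0.782).

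**Figure D5:**
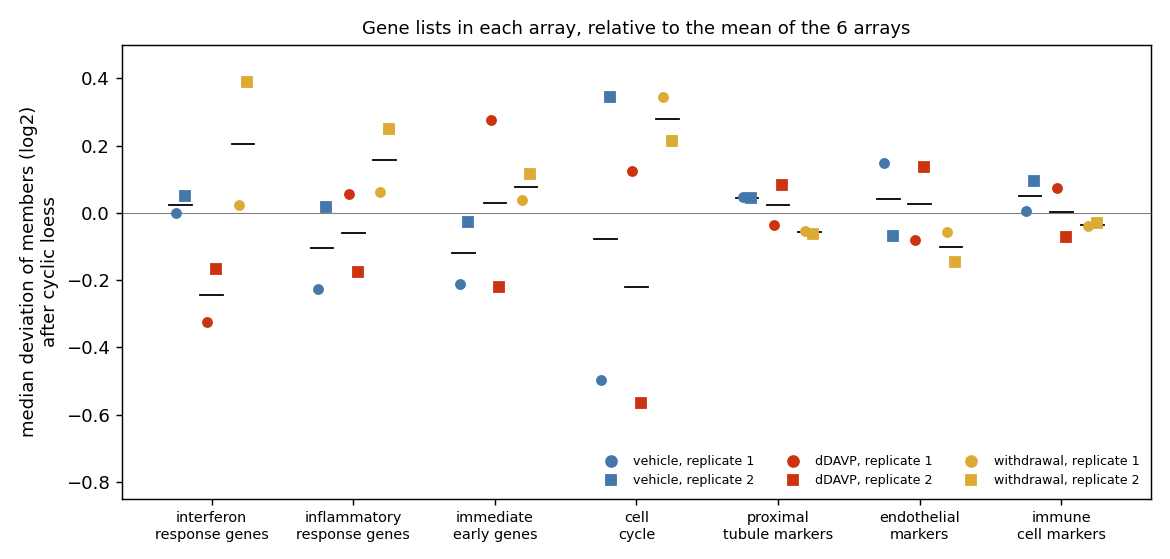
Median deviation of the members of 7 gene lists from their mean over the 6 arrays, after cyclic loess (log2), for each array, with a bar at the mean of each group. The interferon list is lowest in both dDAVP arrays (-0.32 and -0.17), and the cell cycle list is lowest in vehicle replicate 1 and dDAVP replicate 2 (-0.50 and -0.56).

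The third comparison, withdrawal against vehicle, set the tissue 3 h after removal against rats that had never received dDAVP. Here too the removal under anaesthesia cannot be told apart from the infusion and its end. The inflammatory response genes rose as a list, with a median difference of 0.29 (0.27 after loess), and 22 of 26 members were above 0 after loess, among them C3 (0.29 ± 0.09) and Lif (0.31 ± 0.12). Immediate early genes, which respond within minutes to stimuli, rose as a list by a median of 0.24 (0.25 after loess), with 35 of 39 members above 0 after loess. In this list the nuclear receptor Nr4a1 was at 7.82 ± 0.86 in vehicle and 8.99 ± 0.19 in withdrawal (1.17 ± 0.51, with 7.21 in vehicle replicate 1, the lowest of the 6 arrays, and a difference of 0.56 without it), Jund at 0.33 ± 0.12 and Fos at 0.54 ± 0.40. Target genes of the cAMP response element rose as a list by 0.20 (0.15 after loess), among them Pde10a (0.31 ± 0.12) and the growth factor Areg (0.42 ± 0.18). This list shares members with the immediate early list, among them Fos and Nr4a1, so their calls are not independent. The cell cycle list rose by 0.46 (0.43 after loess), with Ccne2 at 0.37 ± 0.16 and Kif23 at 0.56 ± 0.27, and the interferon list by 0.16 (0.17 after loess), with Oasl at 0.56 ± 0.18 and Usp18 at 0.32 ± 0.14. Vehicle replicate 1 and dDAVP replicate 2, the arrays that stand apart, had the lowest loess medians of the 6 in the inflammatory list (-0.23 and -0.18), the immediate early list (-0.21 and -0.22) and the cell cycle list (-0.50 and -0.56). No member of any list passed, neither over all genes nor adjusted over its list alone.

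These 5 lists were called by camera with the preset correlation as deposited and after loess, with adjusted p-values of 9.5e-06 for the inflammatory, 0.00013 for the immediate early, 0.0098 for the cAMP response element, 1.6e-06 for the cell cycle and 0.0164 for the interferon list as deposited. With an estimated correlation the adjusted p was 0.786 for the first 3, 0.793 for the cell cycle and 0.879 for the interferon list. Only the inflammatory list of the 5 kept its call without each single array (adjusted p at most 0.0480). Without vehicle replicate 1, an array that stands apart, the calls of the immediate early (adjusted p = 0.122), cAMP response element (0.0999), interferon (0.405) and cell cycle lists (0.648, in the other direction) were lost. Without withdrawal replicate 2 those of the cAMP response element (0.179) and interferon lists (0.122, in the other direction) were lost. Without both arrays that stand apart the inflammatory (0.0308) and immediate early lists (0.0149) were called and the other 3 were not. The medians moved with single arrays. Without vehicle replicate 1 they were 0.19 for the inflammatory, 0.15 for the immediate early, 0.07 for the interferon and 0.04 for the cell cycle list. Without vehicle replicate 2 they were 0.36 for the immediate early, 0.26 for the interferon and 0.82 for the cell cycle list. Without withdrawal replicate 1 they were 0.31 for the cAMP response element and 0.30 for the interferon list, and without withdrawal replicate 2 they were 0.17 for the inflammatory, 0.08 for the cAMP response element and -0.04 for the interferon list.

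Markers of 3 cell types fell as lists against vehicle, and were also called after loess. The median difference was -0.08 for proximal tubule (24 markers, adjusted p = 0.0017), -0.14 for endothelium (14 markers, adjusted p = 0.0025) and -0.14 for immune cells (24 markers, adjusted p = 0.0114). With an estimated correlation the adjusted p was 0.799, 0.793 and 0.786. Without both arrays that stand apart the endothelial call was lost (0.0981), and with the dimmer genes dropped the immune call was lost (0.536) and too few proximal tubule markers were left for the test. The proximal tubule call was lost without vehicle replicate 1 (0.0549, median -0.05), the endothelial call without the same array (0.129, median -0.03, and a median of -0.23 without vehicle replicate 2), and the immune call without vehicle replicate 2 (0.157, median -0.07) or withdrawal replicate 1 (0.149). Among these markers Hao2 was at -0.59 ± 0.15, the amino acid transporter Slc7a13 at -0.99 ± 0.42, Tek at -0.54 ± 0.19, Pecam1 at -0.34 ± 0.14 and Laptm5 at -0.32 ± 0.12, whereas the neutrophil gene S100a9 was at 0.48 ± 0.18. Cullin and F-box subunits were also called lower (median -0.04, adjusted p = 0.0113, adjusted p = 0.786 with an estimated correlation), but not after loess (adjusted p = 0.209), with the dimmer genes dropped (0.276), nor without vehicle replicate 2 (0.686) or withdrawal replicate 1 (0.145), and Fbxo8 (-0.34 ± 0.13) and Cdc23 (-0.30 ± 0.12) were members. After loess 11 lists were called, 8 higher and 3 lower, against 5 and 4 as deposited. The 3 added by loess were glucocorticoid responsive genes (median 0.15), endoplasmic reticulum stress genes (0.12) and ribosomal proteins (0.06). In replicates 1 and 2 the stress list had loess medians of -0.15 and 0.05 in vehicle and 0.10 and 0.004 in withdrawal. The ribosomal list had -0.005 and -0.02, and -0.007 and 0.10. The arrays of the 2 groups thus overlapped in both lists. The glucocorticoid list had -0.08 and -0.01, and 0.06 and 0.05. No list was called after loess with an estimated correlation (smallest adjusted p = 0.756).

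No gene passed in withdrawal against vehicle (limma, smallest adjusted p 0.995), and 253 genes had an unadjusted p under 0.05, 91 higher and 162 lower, fewer than the 708.4 that chance gives, or 298 after loess, 116 higher and 182 lower. The count was 665 without vehicle replicate 2, 608 without withdrawal replicate 1, 411 without either 1 of the dDAVP arrays and 117 without withdrawal replicate 2. More genes were higher than lower without vehicle replicate 1 (141 of 200), without vehicle replicate 2 (387), without withdrawal replicate 1 (367), without both arrays that stand apart (137 of 253), with an intensity trend (191 of 303, or 176 of 293 with robust fitting) and in the ordinary contrast (304 of 449). At least 1.5-fold apart with an unadjusted p under 0.05 were 9 higher and 21 lower genes, or 8 and 14 after loess, and this count of 30 became 14 without vehicle replicate 1, 220 without vehicle replicate 2, 68 without either 1 of the dDAVP arrays and 174 without withdrawal replicate 1. The higher genes with the smallest p, none passing, were Fmo5 (2.02-fold, 1.01 ± 0.23), Pclaf (1.00 ± 0.39), Zmym6 (0.90 ± 0.22, with -0.04 for its other probe set), Noct (0.80 ± 0.30), the cytokine Csf3 (0.79 ± 0.22), Prl3b1 (0.72 ± 0.24), the protease Adamts1 (0.66 ± 0.20) and Postn (0.59 ± 0.14). The lower genes were the T cell receptor component Cd3g (2.22-fold, -1.15 ± 0.37), Ccl6 (-0.93 ± 0.28), the endothelial transcription factor Erg (-0.90 ± 0.24), Slc7a12 (-0.75 ± 0.22), Cyp4a3 (-0.73 ± 0.15), Fmo1 (-0.68 ± 0.14), Cryz (-0.60 ± 0.11) and Hao2. Single arrays were extreme in the first 2 of these. Cd3g was at 9.30 and 8.57 in vehicle and 7.36 and 8.21 in withdrawal, and Ccl6 at 9.73 and 8.93 in vehicle and 8.51 and 8.29 in withdrawal. Aqp2 differed from vehicle by -0.01 ± 0.10, Avpr2 by -0.21 ± 0.16, Slc14a2 by 0.24 ± 0.30, Aqp4 by 0.13 ± 0.21, Scnn1b by 0.08 ± 0.17, Scnn1g by 0.11 ± 0.14 and Sgk1 by 0.03 ± 0.20. Nedd4 was at -0.23 ± 0.09, Nedd4l at -0.02 ± 0.15, Rnf40 at 0.09 ± 0.10 and Mylip at -0.13 ± 0.13.

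The moderated F-test for any difference among the 3 groups called no gene (limma, smallest adjusted p 0.489), with 1224 genes at an unadjusted p under 0.05. Arrays of 14168 genes were also simulated with each gene's residual variance over all 3 groups. The limma test of dDAVP against vehicle recovered none of 200 genes changed by 0.58 log2, 65% at 1 log2 and 94% at 2 log2.

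Whether the infusion differences turned back after withdrawal was measured across genes. The differences of dDAVP against vehicle and of withdrawal against dDAVP had a Pearson correlation of -0.61 across 14168 genes, which are not independent replicates, and both hold the same dDAVP arrays. Arrays simulated with no group effect gave -0.50. The covariance was -0.0207, against -0.0182 in the simulations (from -0.0249 to -0.0149), a difference of -0.0025 (simulated SD 0.0013) that became 0.0018 after loess. Of the 1000 simulations, which take genes as independent, 38 gave a covariance as low. The simulations also gave the 3 groups the same spread. The SD of the log2 difference between a group's 2 arrays was 0.303 in dDAVP, 0.273 in vehicle and 0.223 in withdrawal. The covariance that comes from shared arrays depends on the spread of the dDAVP arrays, so the simulations understate it. The difference therefore cannot show a reversal. The same difference, of the covariance from that expected of shared arrays, was -0.0153 without dDAVP replicate 1 and -0.0103 without vehicle replicate 1. It was -0.0096 without dDAVP replicate 2, 0.0048 without vehicle replicate 2 and -0.00067 without withdrawal replicate 1. Without withdrawal replicate 2 it was 0.0014, and without both arrays that stand apart -0.0105. Its sign and size thus varied with the arrays left out.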

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

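The number of arrays limits the precision of these results, and how far the signals lay above background is unknown. Leaving out both arrays that stand apart, the crossed pairing, and cyclic loess with an estimated correlation were chosen after seeing the data. Where an array was left out, the lone array of its group was assumed to vary like the other groups. Among gene counts, no gene passed with dim genes dropped, loess, median subtraction, an intensity trend with or without robust fitting, array weights, every probe set, probe set means, the ordinary contrast, the 4 arrays compared, or without the 2 arrays apart. Leaving out single arrays gave 0 to 2 genes in dDAVP against vehicle, in withdrawal against dDAVP and in the F-test, the 2 genes only without dDAVP replicate 1, through single values of dDAVP replicate 2. Of 2820 alternative values of 156 gene results, 2781 kept their sign and 39, in 19 results, did not, and 13 were called, all under the crossed block.

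Called lists numbered 16, 12 and 9 in the order of the report. They numbered 0, 0 and 0 with an estimated correlation, with fry, and with loess plus an estimated correlation. In the first 2 comparisons they numbered 2 and 6 after loess, and 1 and 4 with the lower 0.5 of genes by level dropped. Without both arrays apart they numbered 7, 18 and 17. Leaving out single arrays gave 3 to 24, 10 to 17 and 11 to 14. Of list tests that turned, in dDAVP against vehicle intercalated cell markers did without vehicle replicate 1 (0.933), immediate early genes without dDAVP replicate 1 (0.331) and thick ascending limb markers without both arrays apart (0.780), and the ribosomal list after loess (0.903). The inflammatory list in withdrawal against dDAVP had an adjusted p of 0.818 without both arrays apart. In withdrawal against vehicle, single left-out arrays gave the interferon list 5.97e-10 to 0.405, turned without withdrawal replicate 2 (0.122), and the cell cycle list 5.77e-17 to 0.648, turned without vehicle replicate 1. The cause was not tested.

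The covariance difference for the reversal was -0.0025, and 0.00306 with the dimmer genes dropped, 0.00182 after loess, -0.0105 without both arrays apart, and -0.0153 to 0.00482 without single arrays. The cause of these changes was not tested. Each value takes the spread as equal in the 3 groups, although it was widest between the dDAVP arrays, so none can show a reversal.

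The replicate number pairs nothing in the labels, and same-numbered arrays deviated with correlations of -0.623, -0.0021 and -0.111. With it as a block, 0 genes passed in each comparison and 17, 12 and 9 lists were called. The covariance difference within a replicate block, which also takes the spread as equal, was -0.0106 for number 1 alone and -0.0335 for number 2 alone. A crossed block over the 4 arrays of dDAVP against vehicle, added after that check and pairing arrays that resemble each other, called 43 genes, 7 higher and 36 lower.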

Other observations

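The tests of explanations in this part were chosen after the values were seen, whereas the list tests, with all arrays or with single arrays left out, were planned. Some genes stood out in withdrawal replicate 2 alone. The stromelysin Mmp3 had a log2 intensity of 11.77 there against at most 8.29 in the other 5 arrays, the collagenase Mmp13 9.71 against at most 8.08, and the cytokines Il6 9.37 against at most 6.99 and Il11 9.03 against at most 7.44. Klkb1 (8.53), Pnoc (8.10), Rps24 (11.92) and Prss22 (9.35) stood out in the same array, and no theme was tested. Other genes were extreme in dDAVP replicate 2, which had the highest levels of the loop of Henle genes Umod (11.18 against at most 10.50) and Egf (10.34 against at most 9.27). Atg10 was at 5.98 in dDAVP replicate 1 and at least 8.52 elsewhere, and RT1-N2 at 8.32 in withdrawal replicate 1 and at least 10.16 elsewhere. These genes were chosen after their values were seen.

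Vehicle replicate 1 and dDAVP replicate 2 had the lowest 2 loess medians of the 6 arrays in 10 of the 27 function lists and the highest 2 in 2. The cholesterol synthesis list was at -0.22 and -0.28 and the endoplasmic reticulum stress list at -0.15 and -0.17 in them, whereas erythrocyte markers were at 0.34 and 0.23 and endothelial markers at 0.15 and 0.13. The antigen presentation genes Cd74 (9.99 and 9.86, against at most 9.39) and RT1-Da (10.87 and 10.49, against at most 9.84) were higher in them and the macrophage gene Cd68 (9.33 and 9.29, against at least 10.12) lower. These 3 genes were chosen after their values were seen, and the immune marker list that holds them did not set the 2 arrays apart (loess medians of 0.006 and -0.073).

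These 2 arrays, from different groups, lay more than 1 log2 away from all of the other 4 in 40 genes. They correlated with each other at 0.994 across genes, against 0.987 within vehicle and 0.985 within dDAVP, but vehicle replicate 2 and withdrawal replicate 1 correlated at 0.996, and each of the 6 arrays was nearest to an array of another group. Scaling was argued against, since the deviations of same-numbered vehicle and dDAVP arrays correlated at -0.632 after loess. Another kidney zone in place of inner medulla could not be decided. The median of 13 principal cell markers lay -0.0305 from the other 4 arrays in the array farther from 0 (SD over markers 0.27). Collecting ducts pass through other zones too, so these markers cannot tell the zones apart. Thick ascending limb markers, not part of this test, had loess medians of -0.04 in vehicle replicate 1 and 0.25 in dDAVP replicate 2, the highest of the 6. Labels exchanged between the groups stay open. The lowest dDAVP level of Aqp2 lay 0.0719 above the highest vehicle level. This gap is too small to decide in the brightest probe set of both dDAVP arrays, where a difference can be compressed. The interferon genes were lowest in both labelled dDAVP arrays in 16 of 25 cases. They are correlated with each other, and their pattern was found with these same labels, so it cannot decide either. No biological explanation was tested, as no label sets these arrays apart.

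Dim genes were lower in both dDAVP arrays. Probe sets with no listed gene followed the named genes to within 0.0334 log2 in each of 10 classes of level in dDAVP against vehicle and to within 0.0531 in withdrawal against dDAVP, past the 0.05 set for agreement, so an intensity-dependent array effect stays open. An effect of the infusion on dim genes stays open too, since the lowest median of the other arrays lay 0.0805 above the highest of the dDAVP arrays, which an array effect in both would also give. Array effect and group cannot be told apart here.

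Interferon response genes were lower in both dDAVP arrays. The dim-gene shift was argued against as the whole cause, since the median stayed at -0.284 after loess. Fewer immune cells stay open. The median immune marker lay 0.171 above the median interferon gene, narrowly past the margin set, the SD of 0.163 over the markers. That SD does not measure the error of a difference between medians, so the test cannot decide. The immune markers fell too, with a median of -0.11 after loess and 16 of 24 below 0. With any 1 of the 4 vehicle and dDAVP arrays left out the median as deposited lay from -0.38 to -0.20, with at least 23 of 25 members below 0, though the call was lost without vehicle replicate 2 (adjusted p = 0.249). With an estimated correlation the list did not pass (adjusted p = 0.623).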
